A study of Arabidopsis thaliana with 2 samples.

How the data were processed

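Leaf cells of Arabidopsis thaliana, accession Col-0 and wild type, were profiled as protoplasts, which are cells freed of their walls by enzymes. Per the labels, plants grew in short days, the abaxial epidermis was peeled off the leaves, and the remaining tissue was digested with cellulase and macerozyme. The series design says that vascular cells were enriched to map the leaf vasculature. Per the labels, 2 libraries were made as biological replicates with 10x Genomics Chromium 3' chemistry and sequenced on a NextSeq, with about 7000 protoplasts aimed at in each. The files hold 4287 barcodes for library 1 and 2013 for library 2. A barcode was given to a library by the number at its end, which is the number in the library's title and in its replicate description. No other sample or group is named, so every comparison is between classes of cells within the same 2 libraries. The labels do not say which plants or digestions stand behind each replicate.

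The deposited matrix holds a count of unique molecular identifiers (UMIs) for each gene and barcode, as whole numbers with no normalization, written by Cell Ranger 3.0.2 per the submitters' processing notes and the file header. The genome build, the annotation, the barcode filter of the authors and any downsampling between libraries are not given in the sources used here. The matrix has 32833 gene loci, 22417 of them with at least 1 UMI, and names genes by locus only. Symbols were taken from the TAIR10.1 annotation, which was used for nothing else: all 380 entries of the fixed lists had their locus in it, out of its 32548 loci, and 347 entries had the same symbol or synonym there. Genes whose transcripts are nearly identical (CYP79F1 and CYP79F2, GOX1 and GOX2, PIP2;2 and PIP2;3, and the AOC genes) cannot be told apart with certainty by reads from transcript ends, so values of 1 member alone are uncertain.

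Barcodes were kept with at least 300 genes detected and at most 5% of UMIs from mitochondrial genes. The gene minimum removed 224 barcodes and the mitochondrial limit removed 0. Scrublet, run per library within scanpy 1.11.5, called 3 of the remaining 6076 barcodes doublets (0.049%). So low a share does not show that the caller separated doublets, so doublets must be assumed to remain among the cells. The 6073 kept cells (4159 in library 1, 1914 in library 2) had median depths of 9663 and 16948.5 UMIs and medians of 2305 and 3081.5 genes. The totals over all barcodes were 87932220 and 54902703 UMIs, and 7 barcode sequences occurred in both libraries.

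To keep the genes that define a class apart from the genes tested between classes, clustering drew on a pool of 16176 genes. It held 92 fixed markers of 13 classes and a random draw from the nuclear genes outside the gene lists. The 2000 most variable genes of this pool, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 were used (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15; figures with matplotlib 3.10.9). No batch correction was applied, since no cluster of the size examined took over 90% of its cells from 1 library. A cluster was named by its mean log2 ratio over the markers of a class, with a pseudocount of 10 CPM (counts of a gene scaled to a common total), against the mean of the other clusters, or for mesophyll against the 20th percentile of clusters. The score had to reach 0.8 (mesophyll 2), and at least 3 markers with at least 5 UMIs had to be at least doubled with a pseudocount of 1 CPM. Clusters of at least 80 cells with the markers of more than 1 class other than mesophyll were clustered again. A cluster that met the mesophyll rule and 1 other, as the bundle sheath-like cluster did, was not split. Shallow clusters with no marker of their class among their 10 leading genes stayed unnamed. Markers among these leading genes also ranked the cell types where more than 1 qualified. A cluster of any depth with more such markers of another class was to stay unnamed. These 2 further rules changed no name in the main clustering. The markers and the resolution were fixed before the data were examined, but not this scoring. It went through 3 versions, all set with the clusters in view and before any test between classes. The leading genes of clusters, some of them members of the tested lists, were visible at that stage. Among these were SWEET13 and UMAMIT genes, and CYP83B1 and PIP2;2 in the bundle sheath-like cluster. The first and second versions were run as alternatives. Class names are therefore written with "-like".

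Counts were summed per class and library for the 7 classes with at least 20 cells in each library, which gave 14 sums. Genes past filterByExpr were scaled by the trimmed mean of M values (TMM) and compared with the quasi-likelihood F test of edgeR 4.0.16 (robust, its earlier quasi-dispersion) in R 4.3.3. The library was a block, and 6 residual degrees of freedom were shared by all classes. The design had left open whether scaling precedes or follows the filter. Simulated data, used before any real test, showed a bias when scaling came first. The order chosen was biased too: unchanged simulated genes had a median log2 of -0.13 for phloem parenchyma-like and -0.10 for epidermis-like against mesophyll-like cells, and -0.04 and -0.03 with singleton pairing. The 6498 genes tested belong to the genes outside this draw or to the lists, and none was a clustering gene or a marker. The rule on the leading genes of shallow clusters did rank members of the tested lists too. Clusters C15a, C8 and C6d stayed unnamed by it, with AAP2, GLDP1 and PIP2;2 among their leading genes. To that extent list genes entered the naming. The Benjamini-Hochberg adjustment ran over these genes within each of 5 comparisons, with calls at an adjusted p under 0.05. CPM are taken over TMM-scaled totals and given as the mean and SD of 2 libraries (n = 2), and fold changes are log2 values with a standard error (SE). The SE was worked back from the test, as the absolute log2 value over the square root of F, and is approximate where a class has few UMIs. For a gene with 0 UMIs in 1 class the fold is a bound that puts 3 counts over that class. It uses UMIs pooled over both libraries, so the deeper library 1 weighs more and it is no bound for either library alone. For 1 to 3 UMIs it is the ratio of counts with a 95% counting interval, which does not cover the spread between libraries. Classes compared came from the same libraries, so the 2 libraries are the replicates and cells are not.

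The 18 gene lists (287 genes) were fixed beforehand: sugar transporters, UMAMIT amino acid exporters, amino acid importers, aliphatic glucosinolate biosynthesis, indole glucosinolate and camalexin biosynthesis, photosynthetic light reactions, Calvin-Benson cycle, photorespiration, cuticular wax and cutin, jasmonate biosynthesis, abscisic acid metabolism and transport, gibberellin metabolism and transport, callose synthases and plasmodesmal PDLP proteins, aquaporins, sulfate and nitrate transporters, plasma membrane proton pumps, lignin biosynthesis, and wounding and protoplasting stress. Each was tested with camera of limma 3.58.1, which compares a list with all other genes, at a preset correlation between genes of 0.01 and, as the alternative, with an estimated correlation. Adjustment ran over the lists within a comparison, and for 126 tests of a list in 1 class against the mean of the other classes, over the lists within a class. Adjusted p-values given for genes are from edgeR and those for lists from camera.

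Genes named in the text follow a rule fixed beforehand: from each called list and each list of phloem transport the 3 called members with the largest change in the same direction in both libraries, then the 4 highest and 4 lowest called genes outside the lists at a mean of at least 50 CPM, and always SWEET13, SUC1, SUC4, UMAMIT18, MYB28 and LOX2, up to 30 genes per comparison. Any other gene named was chosen after its values were seen, and the text says so.

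Counts simulated with the depth of these sums and a spread set per gene gave the precision for a case with few changes. In each simulation 200 genes and 1 list of 20 genes were changed, and all others were alike in both classes. In the data far more differed, with 3611 of 6498 genes called for phloem parenchyma-like against mesophyll-like cells. The shares below and the scaling bias above therefore need not hold for the real comparisons. Of genes changed 4-fold, the test called 77.3% for phloem parenchyma-like against mesophyll-like cells, 69.7% for companion cell-like against phloem parenchyma-like, 90.9% for bundle sheath-like against mesophyll-like, 71.2% for epidermis-like against mesophyll-like and 72.7% for procambium-like against phloem parenchyma-like cells. For genes changed 2-fold the shares were 32.8%, 10.4%, 56.7%, 43.3% and 19.4%. Of the genes called there, 8%, 7.9%, 13.2%, 6.2% and 12.8% were unchanged, above the nominal 5% in each comparison. With a spread taken from the trend over genes, 9.7%, 3.2%, 5%, 5.2% and 5.5% were. Of 100 unmoved lists, camera put 1, 0, 5, 1 and 2 under an unadjusted 0.05.

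The alternatives fixed beforehand were DESeq2 1.42.0 size factors and its Wald test, total UMIs as the scaling, no filter on low counts, no library block, plastid and mitochondrial genes left out of the totals, the genes outside the draw for clustering, Leiden resolutions 0.5 and 2, at least 500 genes and 1000 UMIs per cell, no mitochondrial and doublet filter, and each library alone. Alternatives chosen after seeing the data were the earlier naming rules, no splitting of clusters, classes without stress-led clusters, cells without the 5% highest doublet scores (255 cells removed), cells with at least 3000 UMIs, the later quasi-dispersion of edgeR, and TMM with singleton pairing. The comparison of guard cells with epidermis was left out because no cluster was named guard cell-like. Procambium-like cells stood in for xylem, as fixed beforehand for the case that no xylem-like cluster was named. A set of 31 hydathode-like cells, 5 of them in library 2, and 1404 cells in unnamed clusters were left out of the tests.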

Results

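Mesophyll-like cells were the largest class, and the named cells of the vein made up a small share of both libraries. Mesophyll-like cells were 57.2% of library 1 (95% binomial interval 55.7 to 58.7%) and 66.3% of library 2 (64.1 to 68.4%). Over the alternative clusterings, filters and naming rules this share ran from 40.4 to 70.6% and from 51.0 to 76.8%. Bundle sheath-like cells, from the layer around the vein, were 6.40% and 6.90%, and phloem parenchyma-like cells, which pass sucrose to the cell wall space, were 2.38% and 1.99%. Over the alternatives bundle sheath-like cells ran from 0 to 8.05% and 0 to 8.14%. Phloem parenchyma-like cells ran from 0 to 3.25% and 0 to 3.19%, and procambium-like cells from 0 to 6.25% and 0 to 4.91%. Companion cell-like cells were 1.06% and 1.2% (0.433 to 1.95% and 0.627 to 1.99% over the alternatives), procambium-like cells 1.66% and 1.52%, epidermis-like cells 3.46% and 2.93%, myrosin cell-like cells 1.25% and 2.04% (up to 5.63% and 9.40%) and hydathode-like cells 0.625% and 0.261% (up to 2.16% and 2.19%). No cluster was named guard cell, trichome, sieve element, xylem or dividing cell, which does not show that such cells were absent. A sieve element-like class was named in 3 alternatives, with 2.07% and 1.41% of cells at Leiden resolution 0.5, and the second naming rule named 1.49% and 1.36% dividing cell-like. Another 26.0% and 16.9% of cells, with medians of 1020 and 1034 UMIs, lay in unnamed clusters. The share of mesophyll-like cells differed by more than the counting intervals between libraries, and with n = 2 no test was made. The unnamed clusters C0, C8 and C6d had all 11 mesophyll markers raised, with mesophyll scores of 2.379, 2.575 and 2.086. They stayed unnamed as shallow clusters with no mesophyll marker among their leading genes. They held 611, 278 and 62 cells of library 1 and 199, 49 and 16 of library 2. The mesophyll-like share, and its difference between libraries, therefore depended on that rule.

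**Figure D1:**
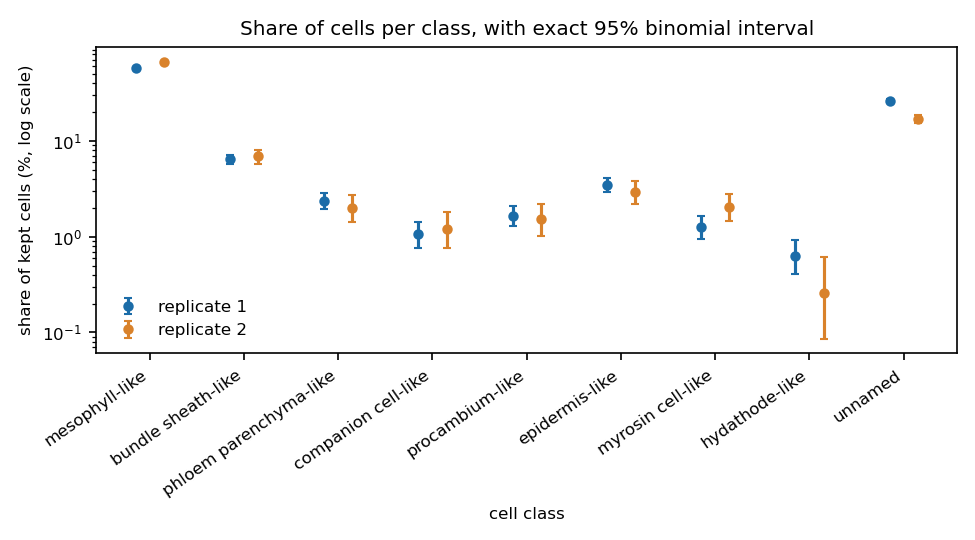
Share of kept cells in each class, per library, with exact 95% binomial intervals. Replicates 1 and 2 are libraries 1 and 2, and classes with 0 cells are left out.

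The class names rest on marker genes that were then left out of every test. For shallow clusters the naming also depended on leading genes, some of them members of the tested lists. Genes that vary together with the markers of a class were still tested, so differences in related lists were partly built into the naming. SWEET11, a sucrose exporter used as a marker, stood at 8123 ± 423 CPM in phloem parenchyma-like, 923 ± 1292 in companion cell-like, 148 ± 195 in procambium-like and 2.23 ± 0.0943 in mesophyll-like cells (mean ± SD, n = 2). In companion cell-like and procambium-like cells the SD exceeded the mean, so 1 library held most of the signal. RBCS1A, a small subunit of Rubisco, stood at 128100 ± 17060 CPM in mesophyll-like, 37080 ± 3206 in bundle sheath-like and 5689 ± 424 in phloem parenchyma-like cells. Bundle sheath-like cells came from 1 cluster with 3 of 4 markers raised (score 0.944), which also met the mesophyll rule with all 11 markers (score 2.05). The marker IQD22 was not among them, at 3.84 CPM against 35.2 in mesophyll-like cells. The larger cluster of procambium-like cells (88 cells) had all 10 procambium markers raised (score 2.101) and all 6 markers of dividing cells (score 2.554). It was named procambium-like because the naming rule put cell types before the dividing state. The smaller cluster (10 cells) was led by genes such as MYB108, ABR1 and JAZ10. Phloem parenchyma-like cells came from a cluster of 100 cells with a median of 3012.5 UMIs and a cluster of 37 cells led by the stress genes PMZ, DREB2C and DREB2B. The smaller cluster held 682844 UMIs and the larger 530374, so the stress-led cells gave more of the summed counts. Without them 76.1% of the main calls tested again were kept against mesophyll-like cells. For companion cell-like and procambium-like against phloem parenchyma-like cells 77% and 63% were kept. The markers and leading genes named here were chosen after their values were seen.

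Phloem parenchyma-like cells held far more RNA of amino acid exporters and of glucosinolate biosynthesis than mesophyll-like cells, and less of photosynthesis. SWEET13, a sucrose exporter, was neither a clustering gene nor a marker. It stood at 418 ± 46.8 CPM against 0.0639 ± 0.0255 CPM (mean ± SD, n = 2 libraries, log2 fold change 12.28, SE 0.51, adjusted p = 1.66e-08). UMAMIT18, an amino acid exporter, stood at 285 ± 121 against 0.0820 CPM (log2 11.10, SE 1.21, adjusted p = 0.00218). MYB28, a transcription factor that activates aliphatic glucosinolate genes, stood at 340 ± 37.7 against 6.67 ± 0.548 CPM (log2 5.67, SE 0.50, adjusted p = 1.32e-05). PSAO, a subunit of photosystem I, stood at 685 ± 11.1 against 17387 ± 1870 CPM (log2 -4.66, SE 0.29, adjusted p = 9.05e-09).

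All 11 measured UMAMIT exporters were higher in phloem parenchyma-like cells, and all 11 also when adjusted over the list alone. Their median log2 fold was 10.57 (10.39 with bounds for genes at 0), with adjusted p = 1.56e-06. The adjusted p was 0.0679 with an estimated correlation, and the library medians were 6.81 and 5.85 on log2(CPM + 1). UMAMIT12 was at 955 ± 459 against 0.324 CPM (log2 11.31, SE 1.05). UMAMIT17, with 0 UMIs in mesophyll-like cells, stood at 171 and 32.8 CPM in libraries 1 and 2 (adjusted p = 3.01e-06). Of 25 aliphatic glucosinolate genes 22 were higher and 0 lower (22 and 1 adjusted over the list alone, median 4.86, adjusted p = 1.5e-09, 0.155 as the adjusted p with an estimated correlation). SOT17 (log2 6.12, SE 0.30) and IPMI_SSU3 (6.54, SE 0.49) were among them. CYP79F2 was at least 305-fold higher, though its reads may come from CYP79F1. All 11 genes of indole glucosinolate and camalexin biosynthesis were higher, also adjusted over the list alone (median 3.98, adjusted p = 2.1e-05, 0.155 as the adjusted p with an estimated correlation). MYB51 (6.79, SE 0.47), CYP79B2 (6.26, SE 0.36) and CYP79B3 (5.44, SE 0.58) had the largest folds.

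Mesophyll-like clusters had been named by 11 markers of photosynthesis, so lower levels of related genes in phloem parenchyma-like cells were partly built into the naming. Every measured gene of photosynthesis was lower in phloem parenchyma-like cells, both over all genes and adjusted over the list alone. These were 22 of 22 in the light reactions (median -4.05, adjusted p = 5.79e-14), 12 of 12 in the Calvin-Benson cycle (median -4.30, adjusted p = 1.94e-07) and 17 of 17 in photorespiration (median -3.49, adjusted p = 1.53e-09). With an estimated correlation the adjusted p was 0.156 for the light reactions and 0.155 for the other photosynthesis lists. Examples are PSAE1 (log2 -4.65), PSAK (-4.62), CP12-2 (-5.64), FBA2 (-5.16), the peroxisomal catalase CAT2 (-5.98, SE 0.54) and the glycolate transporter PLGG1 (-5.74, SE 0.34). Sulfate and nitrate transporters were higher (7 higher and 1 lower of 11, also adjusted over the list alone, median 2.27, adjusted p = 0.00548, 0.155 as the adjusted p with an estimated correlation). Aquaporins were lower (2 higher and 11 lower of 16, 2 and 12 adjusted over the list alone, median -1.59, with bounds -1.54, adjusted p = 0.0161, 0.155 as the adjusted p with an estimated correlation). Jasmonate biosynthesis (8 higher and 1 lower of 14, median 1.42, adjusted p = 0.0337) and wounding and protoplasting stress (6 higher and 0 lower of 10, median 1.06, adjusted p = 0.0351) were higher, with the same counts adjusted over the list alone. For both the adjusted p was 0.155 with an estimated correlation. The 1 jasmonate gene that was lower was LOX2, a chloroplast lipoxygenase, at 10.7 ± 10.9 against 347 ± 29.7 CPM (log2 -4.68, SE 0.43, adjusted p = 1.01e-06).

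Sugar transporters were not called as a list (2 higher and 4 lower of 14, median -0.90, -0.08 with bounds, adjusted p = 0.93). SUC1, a sucrose importer, was lower at 5.73 ± 4.55 against 48.0 ± 2.58 CPM (log2 -3.83, SE 0.99, adjusted p = 0.0127). SUC4 passed the expression filter in no comparison and stood at 10.4 ± 6.40 CPM in phloem parenchyma-like and 0.146 ± 0.141 CPM in mesophyll-like cells. Callose synthases and plasmodesmal PDLP proteins (6 higher and 1 lower of 10, median 1.00, adjusted p = 0.0559) were not called. Neither were amino acid importers (2 and 3 of 12, 0.861), wax and cutin (2 and 1 of 16, 0.93), abscisic acid (4 and 1 of 9, 0.547), gibberellin (1 and 2 of 6, 0.82), proton pumps (2 and 1 of 3, 0.661) or lignin (2 and 7 of 12, 0.533). The test pointed up for importers, wax and cutin and abscisic acid although their medians (-0.45, -1.35 and -0.47) and means were negative. It also did for proton pumps, with a mean of -0.35 and a median of 0.99. Outside the lists, the largest differences were AT1G49470 (3 UMIs in mesophyll-like cells, ratio 8170, interval 2783 to 39723), PAL3, a phenylalanine ammonia-lyase (400 ± 135 against 0.123 CPM, log2 11.08, SE 0.88). In the other direction stood AT5G48490 (3 UMIs in phloem parenchyma-like cells, ratio 359, interval 123 to 1740).

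Of 6498 genes tested, 1663 were higher and 1948 lower in phloem parenchyma-like cells (adjusted p under 0.05, edgeR quasi-likelihood with the library as block). Each gene named had its direction in both libraries, which the naming rule required of all but the genes always named. The calls for jasmonate and wounding genes rested on the stress-led cluster of 37 cells: without it the medians were -0.26 (adjusted p = 0.866) and -0.94 (0.73). With total UMIs and under the second naming rule both calls were lost (jasmonate adjusted p = 0.166 and 0.0537, wounding 0.0967 and 0.175). Jasmonate also lost its call with cells of at least 3000 UMIs (0.0789), and wounding at Leiden resolution 0.5 (0.139) and without the library block (0.0533). The direction of SUC1 turned with the naming rule, the resolution, the removal of the highest doublet scores and without the mitochondrial and doublet filter. The last setting added only 3 barcodes (6076 cells against 6073) but was clustered anew, with 20 clusters against 26. Its changes therefore show unstable clusters and not an effect of the filter. The aquaporin call was lost under both earlier naming rules, where the median turned to 0.19 and 0.23, without the mitochondrial and doublet filter (adjusted p = 0.136) and at resolution 0.5 (0.118). Sulfate and nitrate transporters were not called with total UMIs (adjusted p = 0.0967) or without the highest doublet scores (median 1.12, adjusted p = 0.0756), where the medians of aliphatic and indole glucosinolate genes, still called, were 1.53 and 1.53. Of called genes 79.7% were higher with total UMIs as the scaling against 46.1% with TMM.

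**Figure D2:**
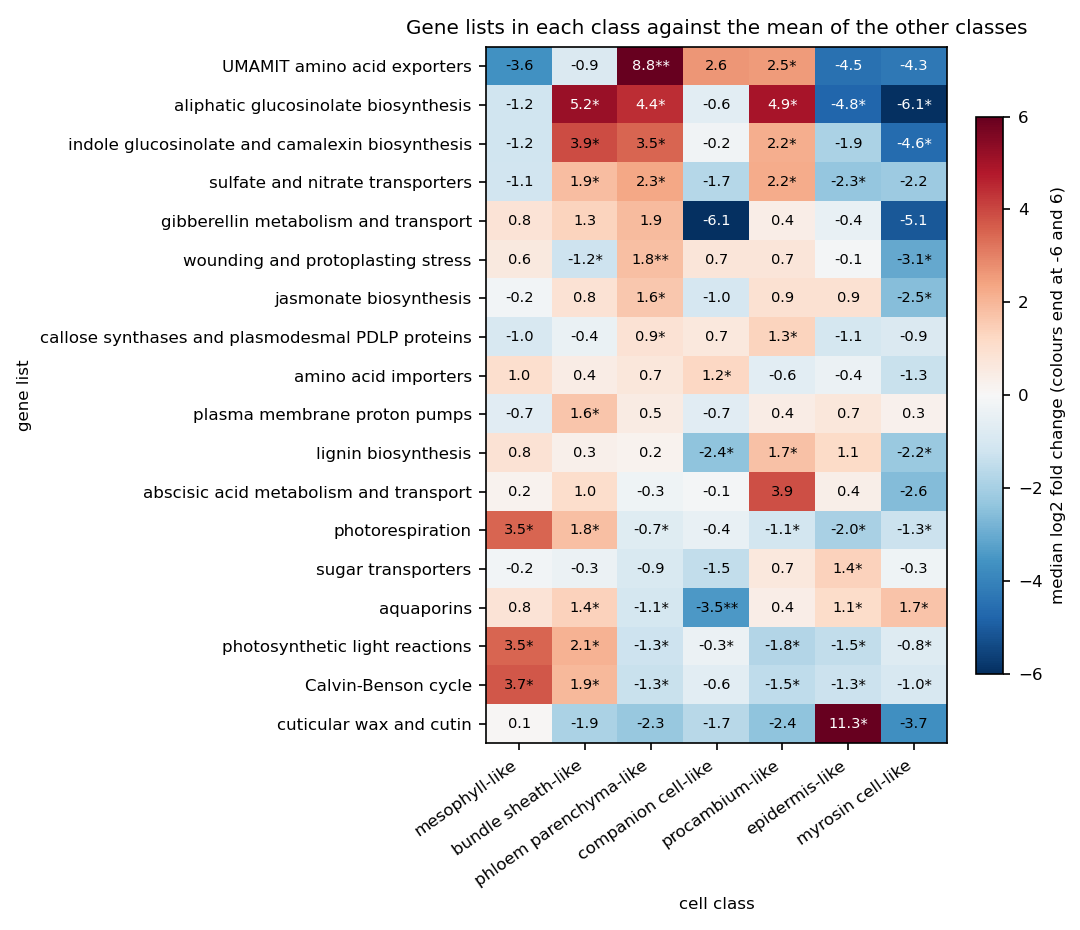
Median log2 fold change of the measured members of 18 gene lists in each of 7 classes against the mean of the other classes. 1 star marks an adjusted p under 0.05 and 2 stars a call that also holds with an estimated correlation, and colours end at 6 and -6.

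Companion cell-like cells held less RNA of amino acid exporters, glucosinolate biosynthesis, lignin biosynthesis and aquaporins than phloem parenchyma-like cells. SWEET13 stood at 13.2 ± 9.02 against 418 ± 46.8 CPM (n = 2, log2 -4.95, SE 0.44, adjusted p = 2.7e-05), and MYB28 at 11.3 ± 16.0 CPM, with UMIs in library 1 only, against 340 ± 37.7 (log2 -4.70, SE 0.61, adjusted p = 0.000671). TIP1;1, an aquaporin of the vacuole membrane, stood at 16.3 ± 6.86 against 190 ± 23.1 CPM (log2 -3.46, SE 0.31, adjusted p = 2.51e-06). SEOa, a sieve element occlusion gene, had 0 UMIs in phloem parenchyma-like cells and was at least 71.4-fold higher at 133 ± 51.6 CPM, a call that was lost in 4 alternatives.

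Of 11 UMAMIT exporters 0 were higher and 7 lower (9 adjusted over the list alone) in companion cell-like cells. Their median was -4.97 (-3.23 with bounds, adjusted p = 1.92e-05, library medians -3.78 and -5.85), and the adjusted p was 0.0873 with an estimated correlation. UMAMIT12 stood at 13.6 ± 19.2 against 955 ± 459 CPM (log2 -5.90, SE 0.95, adjusted p = 0.00519). UMAMIT21 had 0 UMIs and was at least 11.5-fold lower than 40.5 CPM. UMAMIT18 stood at 24.9 ± 35.2 CPM, all in library 1, and did not pass the test (log2 -3.23, SE 1.01, adjusted p = 0.0981). Of 25 aliphatic glucosinolate genes 17 were lower (23 adjusted over the list alone, median -4.05, -4.00 with bounds, adjusted p = 1.96e-13, 0.12 as the adjusted p with an estimated correlation). Of 11 indole glucosinolate and camalexin genes 10 were lower, also adjusted over the list alone (median -3.99, adjusted p = 4.09e-06, 0.0873 as the adjusted p with an estimated correlation). Examples are SOT17 (log2 -5.04, SE 0.42), CYP83B1 (-4.47, SE 0.82) and CYP79B2 (-4.35, SE 0.41). BAT5, a plastid transporter of the aliphatic glucosinolate pathway, had 0 UMIs against 103 ± 2.25 CPM and was at least 38.1-fold lower (adjusted p = 0.00983).

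Of 16 aquaporins 10 were lower in companion cell-like cells (11 adjusted over the list alone, median -2.08, adjusted p = 6.46e-07, 0.0873 as the adjusted p with an estimated correlation). They included PIP1;3 (log2 -3.30, SE 0.28) and TIP2;2 (-3.08). Of 12 lignin genes 8 were lower (9 adjusted over the list alone, median -2.33, adjusted p = 1.14e-05, 0.142 as the adjusted p with an estimated correlation). They included CCOAOMT1 at 83.2 ± 40.8 against 826 ± 139 CPM (log2 -3.36, SE 0.26) and PAL1 (1 UMI, ratio 126, interval 22.3 to 4996). Sulfate and nitrate transporters (1 higher and 8 lower of 11, median -2.57, adjusted p = 0.000191) and jasmonate biosynthesis (1 and 8 of 14, median -2.35, adjusted p = 0.0079) were lower, with the same counts adjusted over the list alone. For both the adjusted p was 0.0873 with an estimated correlation. Wounding and protoplasting stress was lower (0 and 3 of 10, also adjusted over the list alone, median -0.81, adjusted p = 0.0345, 0.142 as the adjusted p with an estimated correlation). The light reactions were higher (13 of 22, 20 adjusted over the list alone, median 0.80, adjusted p = 1.83e-06, 0.313 as the adjusted p with an estimated correlation), led by ferredoxin FD2 at 733 ± 108 against 174 ± 10.9 CPM (log2 2.07, SE 0.20). So were 3 of 12 Calvin-Benson genes (4 adjusted over the list alone, median 0.61, adjusted p = 0.0447, 0.456 as the adjusted p with an estimated correlation). No background of free RNA was measured, so part of the photosynthesis UMIs in both classes may come from mesophyll cells.

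Sugar transporters (2 higher and 4 lower of 14, adjusted p = 0.171), amino acid importers (4 and 1 of 12, median 0.22, 0.122) and gibberellin genes (0 and 1 of 6, median -7.00, -1.68 with bounds, 0.109) were not called as lists, nor were the remaining 5 lists (adjusted p from 0.183 to 0.713). Importers were called without the highest doublet scores (median 1.84, adjusted p = 0.0077), with total UMIs (-0.17, 0.0305) and without the library block (0.21, 0.035). The abscisic acid list had a median of -0.66, a mean of 0.25 and a test pointing down. SUC1 (4.94 against 5.73 CPM, log2 0.31, SE 1.90, adjusted p = 0.961) and LOX2 (19.0 against 10.7 CPM, log2 0.38, adjusted p = 0.693) did not differ detectably, but SUC1 depended on the clustering and stood at -4.10 to -5.47 in 5 alternatives. Outside the lists, TET6 (112 ± 48.0 CPM, at least 53.8-fold) was higher, as was AT1G08160 with 314 CPM in library 1 but 16.0 in library 2 and 0 UMIs in phloem parenchyma-like cells. MIPS1, which makes inositol phosphate (17.8 ± 8.99 against 890 ± 256 CPM, log2 -5.61, SE 0.39), and WRKY18 (log2 -5.49, SE 1.34) were lower. Of 6498 genes 967 were higher and 797 lower in companion cell-like cells (edgeR), or 54.8% higher, against 528 and 1513 (25.9%) with total UMIs as the scaling. SEOa and AT1G08160 were not called higher with the Wald test of DESeq2 (adjusted p = 0.26 and 0.27), without the mitochondrial and doublet filter (log2 -0.03 and 0.39), without the highest doublet scores (-0.002 and 0.25) or at Leiden resolution 0.5. The Calvin-Benson call was lost with total UMIs (median 0.06, adjusted p = 0.0843, light reactions 0.25), under the first and second naming rules (adjusted p = 0.343 and 0.0594) and without the stress-led cluster (0.115). The wounding call was lost under both naming rules (0.223 and 0.0625). Without the stress-led cluster of phloem parenchyma-like cells the jasmonate median was 0.29 (adjusted p = 0.757) and the wounding median 1.26 (0.0273).

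Bundle sheath-like cells held more RNA of glucosinolate biosynthesis and of sulfate and nitrate transporters than mesophyll-like cells and less of photosynthesis. CYP79B3, which makes the oxime precursor of indole glucosinolates, stood at 1172 ± 206 against 27.8 CPM (n = 2, log2 5.42, SE 0.58, adjusted p = 8.95e-05), and MYB28 at 122 ± 15.1 against 6.67 ± 0.548 CPM (log2 4.19, SE 0.46, adjusted p = 0.000117). SULTR3;1, a sulfate transporter of the chloroplast, was 17.0-fold higher at 57.3 ± 1.57 against 3.31 ± 0.605 CPM (log2 4.09, SE 0.22, adjusted p = 1.55e-08). PETC, the Rieske protein of the cytochrome b6f complex, stood at 1852 ± 8.48 against 6584 ± 475 CPM (log2 -1.83, SE 0.23, adjusted p = 2.41e-05).

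All 25 aliphatic glucosinolate genes were higher in bundle sheath-like cells, also adjusted over the list alone (median 5.56, 5.55 with bounds, library medians 4.79 and 5.19, adjusted p = 8.84e-14, 0.327 as the adjusted p with an estimated correlation). GSTF11 (log2 6.52, SE 0.30) and IPMI_SSU3 at 131 ± 14.5 against 1.16 CPM (6.73, SE 0.47) were among them. Of 11 indole glucosinolate and camalexin genes 10 were higher, also adjusted over the list alone (median 4.45, library medians 4.17 and 4.41, adjusted p = 1.79e-06, 0.263 as the adjusted p with an estimated correlation). CYP79B2 (6.02, SE 0.35) and CYP83B1 (4.79, SE 0.60) were among them. Of 11 sulfate and nitrate transporters 7 were higher and 0 lower, also adjusted over the list alone (median 2.25, library medians 2.00 and 2.15, adjusted p = 0.000174, 0.0954 as the adjusted p with an estimated correlation). Among them were NPF2.11, a glucosinolate importer (log2 4.06, SE 0.23), and NPF6.2 at 426 ± 102 against 33.4 CPM (3.67, SE 0.25). All 22 genes of the light reactions (median -1.20, adjusted p = 1.6e-05), all 12 of the Calvin-Benson cycle (median -1.51, adjusted p = 0.00183) and 16 of 17 of photorespiration (17 adjusted over the list alone, median -1.33, adjusted p = 0.000145) were lower. The counts of 22 and 12 were the same adjusted over the list alone, and the adjusted p was 0.423 for each photosynthesis list with an estimated correlation. Examples are PSAK (log2 -1.69), FBA1 (-2.12, SE 0.37), CP12-2 (-1.86, SE 0.43) and CAT2 (-2.07, SE 0.42).

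Aquaporins were not called (8 higher and 4 lower of 16, median 0.69, adjusted p = 0.0922). Neither were UMAMIT exporters (1 and 0 of 11, adjusted p = 0.172), sugar transporters (1 and 3 of 14, median -0.67, -0.37 with bounds, 0.811), jasmonate (5 and 1 of 14, 0.15), lignin (0 and 5 of 12, 0.174), wounding (0 and 5 of 10, 0.3) or the remaining 6 lists (adjusted p from 0.174 to 0.99). Without the stress-led mesophyll-like clusters jasmonate was called higher (median 1.66, adjusted p = 0.00109). The test pointed up for jasmonate and abscisic acid with medians of -0.02 each and means of 0.87 and 0.06. It also did for importers and gibberellin, with medians of 0.02 and 0.29 and means of -0.07 and -0.33. SWEET13 was higher at 1.63 against 0.0639 CPM (log2 4.35, SE 0.78, adjusted p = 0.00115) and LOX2 at 602 ± 39.3 against 347 ± 29.7 CPM (log2 0.80, SE 0.30, adjusted p = 0.0469). SUC1 (24.8 ± 24.2 against 48.0 CPM, adjusted p = 0.113) and UMAMIT18 (2 against 6 UMIs, ratio 1.77, interval 0.175 to 9.92) did not differ detectably. Outside the lists, the cytochrome b5 gene CB5-C (866 ± 90.3 against 17.0 CPM, log2 5.65, SE 0.44) and the ATP sulfurylase APS3 (194 ± 15.3 against 5.01 CPM, log2 5.27, SE 0.28) were among the highest. GPX7, a glutathione peroxidase, was among the lowest (4.31 against 180 CPM, log2 -5.40, SE 0.27).

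Of 6498 genes 1067 were higher and 1815 lower in bundle sheath-like cells (edgeR), and 73 of the 1067 (6.8%) also lay above every other class and the unnamed clusters compared in both libraries. Reclustering without the 5% highest doublet scores (255 cells of all classes) left no cluster named bundle sheath-like. It removed 36 of the 398 cells (9.04%, against 4.20% of all cells), and 358 of those left stayed in 1 cluster of 415 cells, which was named mesophyll-like. With singleton pairing in TMM 1417 were higher and 1418 lower. The size of the photosynthesis difference depended on scaling, with medians of -0.31, -0.62 and -0.44 for the light reactions, Calvin-Benson cycle and photorespiration with total UMIs. There 87.4% of called genes were higher against 37.0% with TMM, and the call for LOX2 was lost in 5 settings.

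Epidermis-like cells held far more RNA of cuticular wax and cutin genes than mesophyll-like cells and less of photosynthesis. The markers that named these classes include the cuticle genes FDH and ABCG11 and 11 photosynthesis genes. Both directions were therefore partly built into the naming. CER1, which makes wax alkanes, stood at 165 ± 21.0 CPM against 2 UMIs in all mesophyll-like cells (ratio 4605, interval 1267 to 38144, n = 2). CER2, a wax elongation gene, stood at 231 ± 8.57 CPM against 2 UMIs (6849, 1888 to 56675). SWEET16, a vacuolar sugar transporter, stood at 106 ± 9.07 against 0.425 CPM (log2 7.90, SE 0.26, adjusted p = 2.31e-09). PSBQ2, a subunit of photosystem II, was lower (log2 -5.03, SE 0.28, adjusted p = 2.97e-09).

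All 16 wax and cutin genes were higher in epidermis-like cells, also adjusted over the list alone (median 9.95, 9.90 with bounds, library medians 7.18 and 7.12, adjusted p = 5.65e-13, 0.148 as the adjusted p with an estimated correlation). LACS2 stood at 104 ± 18.2 CPM against 1 UMI (ratio 6457, interval 1150 to 255880). All 22 genes of the light reactions (median -4.34, adjusted p = 6.87e-14), all 12 of the Calvin-Benson cycle (median -4.30, adjusted p = 2.15e-07) and all 17 of photorespiration (median -4.75, adjusted p = 6.24e-11) were lower, also adjusted over the list alone. The adjusted p was 0.353, 0.148 and 0.051 with an estimated correlation. Examples are PSAE1 (log2 -5.07), FBA2 (-5.48), GAPA1 (-4.97), GLU1 (-5.44) and GLDH3 (-5.12). Sugar transporters were not called as a list (8 higher and 3 lower of 14, 8 and 4 adjusted over the list alone, median 1.01, adjusted p = 0.219). SWEET1 was higher at 48.8 ± 1.65 against 0.0956 CPM (log2 8.43, SE 0.54, adjusted p = 1.17e-06). STP14 stood at 48.3 ± 5.82 CPM against 2 UMIs (ratio 1471, interval 400 to 12270). Of UMAMIT exporters, not called as a list (adjusted p = 0.717), 1 of 11 was higher: UMAMIT5, also named WAT1, at 277 ± 50.7 against 0.731 CPM (log2 8.51, SE 0.33, adjusted p = 1.78e-10).

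Of 12 amino acid importers 4 were higher and 4 lower (adjusted p = 0.93), AAP6 being at least 6.17-fold lower with 0 UMIs against 6.71 ± 0.0313 CPM. Aliphatic glucosinolate biosynthesis (1 higher and 7 lower of 25, median -3.44, -1.50 with bounds, adjusted p = 0.103), jasmonate (8 and 3 of 14, 0.301), aquaporins (9 and 3 of 16, 0.374) and wounding (0 and 0 of 10, 0.93) were not called. The remaining 7 lists had adjusted p from 0.257 to 0.855. The test pointed up for UMAMIT exporters and importers although their medians were -0.17 and -1.09 (0.00 with bounds for each) and their means negative. LOX2 was lower at 66.8 ± 27.8 against 347 ± 29.7 CPM (log2 -2.36, SE 0.33, adjusted p = 4.5e-05). SUC1 (15.9 ± 4.32 against 48.0 CPM, log2 -1.70, SE 0.62, adjusted p = 0.0504) and MYB28 (log2 -2.23, SE 0.99, adjusted p = 0.0856) did not pass. SWEET13 and UMAMIT18 had 0 UMIs in epidermis-like cells against 4 and 6, with no detectable difference. Outside the lists, DCF stood at 774 ± 12.6 against 0.311 CPM (log2 11.32, SE 0.63, adjusted p = 3.71e-05), and LURP1 at 1 UMI was lower (ratio 415, interval 74.5 to 16408). Of 6498 genes 1816 were higher and 1932 lower (edgeR). The aliphatic glucosinolate list was called lower in 7 of the alternative settings, and with total UMIs 81.5% of called genes were higher against 48.5% with TMM.

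Procambium-like cells held more RNA of aquaporins and of lignin biosynthesis than phloem parenchyma-like cells and less of amino acid exporters. PIP2;7, a plasma membrane aquaporin, stood at 891 ± 160 against 109 ± 40.1 CPM (n = 2, log2 2.99, SE 0.27, adjusted p = 2.5e-05). PAL1, at the entry to lignin synthesis, stood at 632 ± 255 against 138 ± 58.5 CPM (log2 2.24, SE 0.53, adjusted p = 0.0216). UMAMIT28 had 0 UMIs in procambium-like cells and was at least 67.7-fold lower than 98.8 ± 25.9 CPM (adjusted p = 0.000881). SWEET13, with UMIs in library 1 only, was lower at 7.31 ± 10.3 against 418 CPM (log2 -5.52, SE 0.44, adjusted p = 6.73e-05). SUC1 was higher at 137 ± 44.5 against 5.73 ± 4.55 CPM (log2 5.27, SE 0.94, adjusted p = 0.00974), though its fold was -1.37 under the first naming rule.

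Of 16 aquaporins 9 were higher and 0 lower in procambium-like cells (12 and 1 adjusted over the list alone, median 0.98, library medians 0.83 and 1.36, adjusted p = 1.47e-05). This call alone among the lists of the 5 comparisons held with an estimated correlation, where the adjusted p was 0.0466. PIP2;8 stood at 255 ± 6.42 against 12.1 ± 17.2 CPM (adjusted p = 0.00244), and PIP2;5 at 43.1 and 14.2 CPM in libraries 1 and 2 against 0 UMIs (adjusted p = 0.00385). Of 12 lignin genes 7 were higher (8 adjusted over the list alone, median 1.70, adjusted p = 0.000438, 0.483 as the adjusted p with an estimated correlation). 4CL1 (log2 2.73, SE 0.40) and C4H (2.32, SE 0.41) were among them. Of 11 UMAMIT exporters 1 was higher and 7 lower (1 and 9 adjusted over the list alone, median -4.26, -3.81 with bounds, library medians -3.47 and -3.40, adjusted p = 0.000438, 0.334 as the adjusted p with an estimated correlation). UMAMIT18 had 0 UMIs and was at least 147-fold lower (adjusted p = 0.0423).

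Smaller differences were called for photosynthesis and stress genes. For the photosynthesis genes no background of free RNA was measured, so part of their UMIs in both classes may come from mesophyll cells. The light reactions (0 higher and 2 lower of 22, also adjusted over the list alone, median -0.44, adjusted p = 0.000438) and photorespiration (0 and 4 of 17, 0 and 9 adjusted over the list alone, median -0.77, adjusted p = 0.00266) were lower. So were wounding (0 and 4 of 10, 0 and 5 adjusted over the list alone, median -0.76, adjusted p = 0.0315) and indole glucosinolate genes (0 and 3 of 11, 0 and 4 adjusted over the list alone, median -1.06, adjusted p = 0.032). The adjusted p was 0.715, 0.665, 0.334 and 0.665 with an estimated correlation. Members are PETE1 (log2 -1.20), PSBR (-0.98), GLDT (-1.11), HPR1 (-1.03), JAZ1 at 331 ± 117 against 1098 ± 182 CPM (-1.72, SE 0.30), ZAT12 (-1.35) and MYB51 (-1.89, SE 0.48). Sugar transporters (2 higher and 2 lower of 14, 0.692), amino acid importers (1 and 2 of 12, 0.452), aliphatic glucosinolate genes (2 and 0 of 25, 0.588), abscisic acid (1 and 3 of 9, 0.808) and sulfate and nitrate transporters (4 and 4 of 11, 0.878) were not called. The remaining 6 lists had adjusted p from 0.566 to 0.965. Abscisic acid had a median of 0.03 and a mean of 2.12 with a test pointing down, and sulfate and nitrate transporters a median of -0.29 and a mean of 0.43 with a test pointing down. Callose and PDLP genes and proton pumps had negative medians (-0.16 and -0.13) with a test pointing up. MYB28 (206 ± 51.4 against 340 CPM, log2 -0.74, SE 0.43, adjusted p = 0.307) and LOX2 (log2 -0.08, adjusted p = 0.975) did not differ detectably.

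Outside the lists, UBC20, a ubiquitin-conjugating enzyme gene (303 ± 170 against 2.09 CPM, log2 6.70, SE 0.53), and MAD2, of the spindle checkpoint (138 ± 68.9 against 2.51 CPM, log2 5.45, SE 0.48), were higher in procambium-like cells. PMZ, a leading gene of the stress-led cluster of 37 cells, was lower (2.19 against 626 ± 88.3 CPM, log2 -7.73, SE 0.62), with a fold of 0.27 once that cluster was left out. Of 6498 genes 603 were higher and 510 lower (edgeR), or 54.2% higher, against 65.8% with total UMIs, 40.2% under the first naming rule and 39.4% at Leiden resolution 0.5. The small differences in photosynthesis and indole glucosinolate genes were not called at resolution 0.5 (adjusted p from 0.164 to 0.194). Under the first naming rule aquaporins were not called (median -0.42, adjusted p = 0.962), and without the highest doublet scores lignin was not (0.75, adjusted p = 0.0804). Without the stress-led cluster the jasmonate and wounding lists were called higher (medians 1.01 and 1.32, adjusted p = 0.00438 and 0.00134), and at Leiden resolution 2 the photosynthesis lists turned direction.

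**Figure D3:**
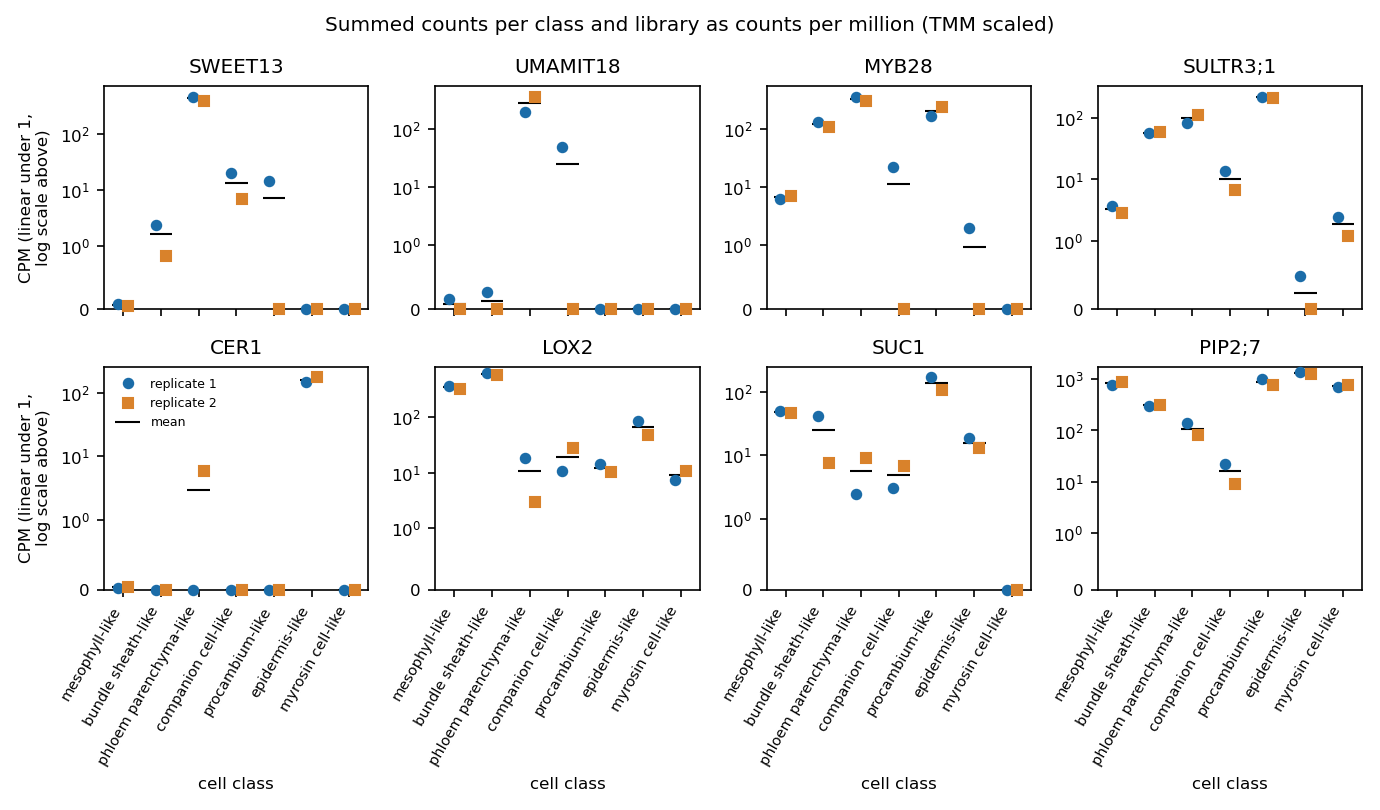
CPM of SWEET13, UMAMIT18, MYB28, SULTR3;1, CER1, LOX2, SUC1 and PIP2;7 in each class, 1 point per library, with a line at the mean. The axis is linear under 1 CPM and logarithmic above.

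Set against the mean of the other classes, 53 of 126 pairs of a list and a class were called. They were 3 in mesophyll-like, 8 in epidermis-like, 9 in myrosin cell-like, 9 in bundle sheath-like, 11 in phloem parenchyma-like, 4 in companion cell-like and 9 in procambium-like cells. Of these, 3 held with an estimated correlation. UMAMIT exporters were higher in phloem parenchyma-like cells (10 of 11, library medians 6.01 and 5.38, adjusted p = 5.87e-11, 0.0489 as the adjusted p with an estimated correlation). Wounding and protoplasting stress was higher in phloem parenchyma-like cells (7 of 10, library medians 1.41 and 1.95, adjusted p = 7.07e-06, 0.0489 as the adjusted p with an estimated correlation). That call rested on the stress-led cluster of 37 cells, without which the test pointed down with adjusted p = 0.443. Aquaporins were lower in companion cell-like cells (14 of 16, library medians -3.41 and -2.91, adjusted p = 4.86e-11, 0.0483 as the adjusted p with an estimated correlation).

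Aliphatic glucosinolate genes were higher than the mean of the other classes in bundle sheath-like (24 of 25, library medians 3.71 and 3.84, adjusted p = 1.95e-13), phloem parenchyma-like (21 of 25, 2.82 and 4.04, adjusted p = 6.93e-16) and procambium-like cells (25 of 25, 3.04 and 4.03, adjusted p = 6.53e-17), with adjusted p of 0.16, 0.0902 and 0.194 with an estimated correlation. They were lower in epidermis-like cells (10 of 25, library medians -3.53 and -3.62, adjusted p = 0.0101, 0.636 as the adjusted p with an estimated correlation). Amino acid importers were higher in companion cell-like cells (6 higher and 1 lower of 12, library medians 0.70 and 0.80, adjusted p = 0.0281, 0.266 as the adjusted p with an estimated correlation). Lignin genes were higher in procambium-like cells (9 of 12, 1.51 and 1.95, adjusted p = 2.67e-05) and lower in companion cell-like cells (10 of 12, -2.48 and -2.43, adjusted p = 1.97e-05), with adjusted p of 0.194 and 0.347 with an estimated correlation. With spreads estimated from 2 libraries, differences missed by the test are not shown to be absent.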

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

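The tests on the UMAMIT exporters in phloem parenchyma-like cells, on genes lower in bundle sheath-like cells and on photosynthesis genes between classes poor in them were chosen only after the result was seen, and the other tests on bundle sheath-like cells and on photosynthesis genes were written down before their results. The samples form 1 group of 2 replicates, so no biological explanation was tested for any pattern.

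Signal lay in cells that no comparison used. Clusters with no class name held 1404 cells (3662530 UMIs, 2.57% of those in kept cells), with C0 (810 cells, median 806.5 UMIs) and C8 (327 cells, median 2713 UMIs) the largest. A cluster of 31 hydathode-like cells, 26 in library 1 and 5 in library 2, had markers NRT2.1, PHT1;4 and PUP1 raised, and SUC1 at 1388 CPM, not scaled by TMM, against 23.82 in mesophyll-like cells. The unnamed cluster C6c (64 and 24 cells, median 873 UMIs) held 62 UMIs of the sieve element markers NEN4 (45) and NAC045 (17), or 674 CPM against 0.0421 in mesophyll-like cells, all of them in library 1 and 0 in library 2. These were listed because they exceed what a count of 0 allows in data outside the comparisons, their differences were not tested, and the genes named were chosen after their values were seen.

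The UMAMIT exporters in phloem parenchyma-like cells could have come from shallow barcodes, from the stress-led cluster of 37 cells or from doublets with companion cells. With cells of at least 3000 UMIs only, the median log2 fold against mesophyll-like cells over 10 measured members was 12.31 (adjusted p = 4.85e-07) against 10.57 with all cells. Without the stress-led cluster it was 10.88 (adjusted p = 6.1e-07). Companion cell-like cells held less of these exporters than phloem parenchyma-like cells (median -4.97, 0 higher and 7 lower of 11, adjusted p = 1.92e-05, 0.0873 as the adjusted p with an estimated correlation), and a mixture has no level above both of its parts. The value with deeper cells argues against shallow barcodes. The outcomes for the other 2 explanations could be foreseen, so they were no independent tests. They show only that the larger cluster held these exporters without the smaller, and that companion cell-like cells held less. UMAMIT30, UMAMIT20, UMAMIT17 and UMAMIT12 already stood among the 10 leading genes of the larger cluster. The companion cell-like values are those of the main comparison and add no new support.

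The differences between bundle sheath-like and mesophyll-like cells might reflect doublets of mesophyll cells with cells of the vein, since a mixture has no level above both of its parts. Of 1067 genes called higher, 73 (6.8%) lay above 6 other classes and 4 unnamed clusters in both libraries, between the bounds of 5% for a mixture and 20% against it. Of 488 genes called lower, 1 (0.2%) lay in both libraries under 1/2 of the least level that a mesophyll share of 0.179 to 0.643, set by the photosynthesis genes, would bring, and looser forms tried before gave at most 1 gene too. Neither test excludes doublets, which remain possible, and of these cells 9.04% had a doublet score among the 5% highest, against 4.20% of all cells and 15.0% of epidermis-like cells. Stress-led mesophyll-like clusters were the other candidate. Without them 91.7% of called genes were called in the same direction, which argues against them as the source of most calls. The balance did move, with 1602 genes called higher and 1616 lower against 1067 and 1815 with all clusters.

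The photosynthesis RNA in phloem parenchyma-like cells could be free RNA from broken mesophyll cells. If that were its only source, its genes would keep 1 ratio to their mesophyll level. Over 51 genes with a median log2 fold of -4.04 the SD beyond their standard errors was 0.87, above the bound of 0.5 set against this explanation. That bound took the mesophyll-like sum as the profile of free RNA, and no background was measured, so it does not decide. RBCS1A stood at 5275 to 7119 CPM in 5 classes, and the SD was 0.23 against procambium-like cells, as a shared background would give, but 0.68 to 0.94 against the other 3 classes poor in these genes. Free RNA as the only source therefore cannot be told apart from RNA of the cells themselves.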

How the results depend on the processing

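Every test described here on naming rules, splitting, stress-led clusters, doublet scores, depth, the later quasi-dispersion and TMM with singleton pairing was chosen only after the result or the data were seen. The markers, lists, tests, filters, resolutions and the other alternatives were chosen before the data were examined. Of 2644 alternative values for 150 named gene results, 2526 kept direction and side of the threshold, 68 lost and 23 gained a call and 27 turned direction. For 90 list results, 1509 of 1620 values were kept, 63 lost a call (36 of them with an estimated correlation), 36 gained one and 12 turned. A change of sign where neither value was called counts as kept. Of 112 shares of cells per class, 39 moved. The share ran over 0 to 8.05% and 0 to 8.14% for bundle sheath-like, 0 to 3.25% and 0 to 3.19% for phloem parenchyma-like and 0 to 6.25% and 0 to 4.91% for procambium-like cells in libraries 1 and 2. The counts of called genes ranged over 3014 to 4470 for phloem parenchyma-like against mesophyll-like, 1643 to 2221 for companion cell-like, 2505 to 3957 for bundle sheath-like, 3008 to 4751 for epidermis-like and 842 to 1680 for procambium-like cells. The highest for the last was at resolution 2 (1680), where 428 of 1012 calls were kept. List calls by class ranged from 3 of 126 tests (estimated correlation) to 70 of 162 (resolution 0.5, 9 classes), against 53 of 126. Clusters of phloem parenchyma-like cells could be tested only with 10 cells per library (447 genes called). Total UMIs moved the median log2 of all genes to 1.23, -0.53, 0.70, 1.21 and 0.13 from -0.11, -0.01, -0.17, -0.09 and 0.01.

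The named share of cells, 76.88%, was 84.84% without mitochondrial and doublet filters, 61.21% with the other genes for clustering, 84.85% and 67.74% at resolutions 0.5 and 2, 84.26% without the highest doublet scores, 83.81% with at least 3000 UMIs, 60.05% without stress-led mesophyll-like clusters. The setting without mitochondrial and doublet filters differed by 3 barcodes only, so all of its changes came with the new clustering. With 1 library there is no test, and 2 values always lie within their SD of the mean, so only signs are compared. For called results, all 188 gene values and 74 list medians of single libraries had the sign of the main value. Apart from the genes always named, the genes had been picked for the same direction in both libraries. Their agreement was therefore largely fixed by the naming rule and is no support. For results not called, 3 of 12 gene values had the opposite sign, and of 106 list medians 16 did and 8 were 0.

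The following medians and log2 folds turned, for lists by the direction of the test, and the cause was not tested. In phloem parenchyma-like against mesophyll-like cells: without the stress-led cluster, jasmonate -0.264 and wounding -0.939, with the second naming rule aquaporins 0.229, and SUC1 0.892 (no mitochondrial and doublet filter), 1.054 and 0.282 (resolutions 0.5 and 2), 2.062 and 2.206 (first and second naming rules) and 0.594 (without highest doublet scores). In companion cell-like cells: without the stress-led cluster, jasmonate 0.287 and wounding 1.262, at resolution 0.5 AT1G08160 -11.154 (a fitted value), SUC1 -4.266, -4.099, -5.473, -5.243 and -4.419 (no mitochondrial and doublet filter, resolution 0.5, first and second naming rules, highest doublet scores removed), and SEOa -0.03, -10.027 and -0.002 (no mitochondrial and doublet filter, resolution 0.5, highest doublet scores removed, the second a fitted value). In procambium-like cells at resolution 2: light reactions 1.318, Calvin-Benson 1.411, photorespiration 1.028, callose and PDLP -0.973, GLDT 0.064, HPR1 1.161, PETE1 0.605, PSBR 0.849, LOX2 3.106 and AGT1 1.131. There, without the stress-led cluster: jasmonate 1.01, wounding 1.324, JAZ1 0.546, ZAT10 2.056, ZAT12 0.884 and PMZ 0.268. With the first naming rule: aliphatic glucosinolate -1.243 and SUC1 -1.373, and without the highest doublet scores AT5G22580 3.194. Other medians changed sign while the test kept its direction: aquaporins with the first naming rule (0.189 in phloem parenchyma-like and -0.416 in procambium-like cells) and indole glucosinolate at resolution 2 (0.122, procambium-like) lost a call. A call was gained by importers with total UMIs (-0.171, companion cell-like), jasmonate without stress-led mesophyll-like clusters (1.659, bundle sheath-like) and, with the first naming rule, abscisic acid (-0.979) and callose and PDLP (0.757) in procambium-like cells.

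Without the library block 3581, 1730, 2776, 3689 and 1070 genes were called in the 5 comparisons. Callose and PDLP (adjusted p = 0.0126, median 0.99 in phloem parenchyma-like cells), importers (0.035, companion cell-like) and sugar transporters (0.00269, epidermis-like) gained a call, and wounding (0.0533, phloem parenchyma-like) and AT1G08160 (0.0881) lost theirs. Pairing follows from the layout. Across 800 to 1224 genes, deviations between libraries correlated at -0.19 to 0.54 (median 0.11) over 21 pairs of classes.

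Some alternatives gave no value because a class fell under 20 cells in a library: phloem parenchyma-like with at least 500 genes (40 and 15 cells), companion cell-like at resolution 2 (18 and 12) and procambium-like with at least 3000 UMIs (21 and 8). No cluster was named procambium-like with at least 500 genes or under the second naming rule, bundle sheath-like without the highest doublet scores, or phloem parenchyma-like with clusters unsplit. Alternatives for guard cells and for phloem parenchyma-like clusters were not run, and 2 libraries allow no other split of the samples. Depth limits rare classes: 2-fold changes were called for 10.4% of simulated genes between companion cell-like and phloem parenchyma-like cells.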

Other observations

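The test between clusters of phloem parenchyma-like cells was run in a form chosen only after the result was seen (at least 10 cells per library in place of 20), and the genes and markers named here were chosen after their values were seen.

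Myrosin cell-like cells, which hold the enzymes that break down glucosinolates, carried little RNA of glucosinolate biosynthesis. Against the mean of the other classes, 12 of 25 aliphatic glucosinolate genes were lower and 0 higher (library medians -3.97 and -3.96 on log2(CPM + 1), adjusted p = 0.000173), as were 9 of 11 indole glucosinolate and camalexin genes (-3.86 and -3.51, adjusted p = 0.00104). With an estimated correlation the adjusted p was 0.372 and 0.273. Epidermis-like cells were nearly as low in the aliphatic list (library medians -3.53 and -3.62), so that trait was not particular to myrosin cell-like cells. The mean of the other classes includes bundle sheath-like, phloem parenchyma-like and procambium-like cells, in which both lists were high. Jasmonate biosynthesis (1 higher and 9 lower of 14, library medians -3.02 and -1.95, adjusted p = 0.00106), wounding and protoplasting stress (0 and 8 of 10, -3.15 and -3.10, adjusted p = 0.000639) and lignin biosynthesis (1 and 8 of 12, -1.98 and -2.21, adjusted p = 0.0118) were lower, with adjusted p of 0.17, 0.175 and 0.372 with an estimated correlation. Aquaporins were higher (10 higher and 2 lower of 16, library medians 1.08 and 1.17, adjusted p = 0.00104, 0.175 as the adjusted p with an estimated correlation). The light reactions (0 and 21 of 22, adjusted p = 1.6e-06), photorespiration (0 and 13 of 17, adjusted p = 2.7e-05) and the Calvin-Benson cycle (0 and 7 of 12, adjusted p = 0.00258) were lower, each with an adjusted p of 0.372 with an estimated correlation. The exporter UMAMIT10 stood at 499 ± 15.2 CPM in myrosin cell-like cells (n = 2).

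Phloem parenchyma-like cells came in a stress-led cluster of 37 cells and a larger cluster of 100 cells. The smaller held more RNA of jasmonate biosynthesis and of wounding genes and less of aliphatic glucosinolate biosynthesis (camera adjusted p = 3.24e-09 for each list) and of aquaporins (adjusted p = 0.0147). No value with an estimated correlation is given for these lists, and in the tests by class that setting kept 3 of 53 calls. The clusters also differed in depth, with medians of 16489 UMIs in the smaller and 3012.5 in the larger. LOX3, a lipoxygenase of jasmonate synthesis, stood at 128.5 and 106.8 CPM in libraries 1 and 2 against 3.238 and 0 (log2 5.62, SE 0.74, adjusted p = 1.07e-06), and AOS, the next enzyme, was higher (log2 3.56, SE 0.52, adjusted p = 3.19e-05), as were ZAT10 (4.39), JAZ1 (3.23), ZAT12 (3.11) and OPR3 (2.58). SWEET13 (log2 -0.40, adjusted p = 0.546), UMAMIT12 (-0.45, adjusted p = 0.697) and MYB28 (-1.11, adjusted p = 0.153) did not differ detectably. Other members did: UMAMIT30 (-1.85, adjusted p = 0.023), UMAMIT5 (-1.81, adjusted p = 0.0466) and MYB29 (-2.70, adjusted p = 0.0241) were lower, and the sugar importer STP13 was higher (2.83, adjusted p = 0.0048). Of 7587 genes 344 were higher and 103 lower. The genes that made the clusters were not tested, but the jasmonate and wounding genes lie in the response that led to the cluster being singled out.

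Some fixed markers stood in classes other than their own. KAT1 and KAT2, potassium channels taken as guard cell markers, stood at 119 ± 57.7 and 31.8 ± 19.1 CPM in companion cell-like cells. SULTR2;1, taken as a companion cell marker, stood at 503 ± 109 CPM in procambium-like and 1.90 ± 0.550 CPM in companion cell-like cells. The trichome marker TRY stood at 50.4 ± 4.59 CPM in mesophyll-like cells, and FAMA, taken as a marker of guard cells and of myrosin cells, at 627 ± 35.2 CPM in myrosin cell-like cells. In the unnamed cluster C16a (49 cells, median 18384 UMIs) BCAT4 stood at 6735 and ACL5 at 216 CPM, not scaled by TMM. In the unnamed cluster C15a (52 cells, median 2136.5 UMIs) PP2-A1 stood at 5024, AAP2 at 3829 and AHA3 at 910 CPM, not scaled by TMM.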
